A study of Rattus norvegicus with 2 samples.

How the data were processed

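Total RNA was taken from microglial cells of Sprague Dawley rats grown in serum-containing medium, at rest or after oxygen-glucose deprivation, and was extracted with TRIzol, per the labels' protocols. Per the labels' protocols, cDNA was primed with oligo(dT) carrying a T7 promoter and transcribed in vitro with biotinylated nucleotides. The platform named in the probe annotation used here is an Affymetrix rat genome expression array. The deposited values are intensities, 1 summarised value per probe set and array on a linear scale, and the authors' background correction, summarisation and normalization are not given in the sources used here. The linear scale was read from the values, which ran from 2.75 to 19692 on the resting array and from 2.73 to 19778 on the OGD array. Both arrays had nearly the same distribution, with quartiles of 8.45 and 48.2 at rest and 8.47 and 48.0 after OGD. Quartiles this close are what scaling of the arrays to each other would leave, but whether and how the authors did so is not given. A difference shared by most genes cannot be seen in such values.

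Groups were taken from the labels, with 1 resting and 1 OGD array. Of 31099 probe sets, 57 array controls were kept apart. Of the others 20826 named 1 gene, 436 named several and 9780 were unnamed in the annotation. Only probe sets naming 1 gene entered the comparison, and symbols were updated through Entrez IDs to those of the RefSeq gene table of assembly GRCr8, in which 20758 of these probe sets had their ID. The files name no genome build, so no coordinates are given. Each of the 14217 genes was represented by the probe set with the highest mean over both arrays, a choice blind to the difference.

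The floor was the median of the non-control probe sets of each array, 4.29 on the log2 scale at rest and 4.30 after OGD. A value under the floor was set to it, a gene was called measured when above the floor on at least 1 array, and a gene above it on 1 array only was given a bound. Differences are log2 OGD minus log2 resting. No test across samples is possible with 1 array per group, so no p-value or standard error is given, and genes were counted at a fixed 1.5-fold, the threshold named in the series' design text. The number of arrays limits the precision, and the only error that could be estimated was the SD between probe sets of 1 gene. It covers noise that differs between those probe sets, not labelling or hybridisation effects they share, and not the spread between cultures.

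Each of 28 gene lists, covering hypoxia, metabolism, stress, inflammation, microglial state, housekeeping functions and markers of other cell types, was described by the median difference of its measured members. Its percentile was taken among 10000 random lists of the same size matched on mean log2 intensity in 20 bins. Lists with fewer than 5 measured members were given no percentile. The lists, the threshold, the floor, the alternatives and the rule for named genes were fixed before the data were examined.

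The rule for named genes took the 12 genes with the largest difference in each direction among those above the floor on both arrays and the 4 with the largest bound in each direction among those above it on 1 array. It also took up to 3 members of each list by absolute difference, and up to 3 in the direction of the median for lists outside the central 95%. Added to these were the reference genes Actb, Gapdh, Hprt1, Tbp, Ppia and B2m, the hypoxia-related transcription factors Hif1a, Epas1 and Arnt, and the activation readouts Tlr4, Tnf, Il1b, Il6, Nos2, Arg1, Vegfa, Aif1 and Itgam. A placeholder locus symbol was passed over, which affected 1 gene. That locus, LOC102553465, and the genes Ifit1, Stat2, Stag2 and Ppp4r3b are named outside the rule and were chosen after their values were seen.

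The calculation was tested on simulated arrays made from the real values with differences shuffled among probe sets of like brightness. Of 25 genes made 2-fold higher 100% were called, and of 25 made 2-fold lower 92% were called, against 80% at 3-fold lower and 84% at 4-fold lower, with the floor limiting lower calls. At a simulated 1.5-fold 48% of higher and 44% of lower genes were called. Among the genes left unchanged in the simulation, of 9585 measured in all, 18 passed 1.5-fold. The shuffled differences are those of the real arrays, so this count is no independent estimate of noise. All 60 simulated lists shifted by 0.2 stood above the central 95%, and 2 of 60 unshifted lists stood outside it.

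Alternatives were floors at the 30th and 70th percentile or no floor, only genes above the floor on both arrays, centring on the median, quantile normalization between the arrays, removal of a loess trend on brightness with a span of 0.3, the mean over probe sets of a gene, leaving out probe sets with suffixes that mark shared or cross-matching probes, and a pseudocount at the 25th percentile. Further alternatives were a count per probe set, a 2-fold threshold, unmatched random lists, lists without their largest member and lists without shared members. The next brightest probe set of each list member was added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.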

Results

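Gene expression was measured in microglial cells, the resident macrophages of the brain, from Sprague Dawley rats on Affymetrix rat expression arrays. One group was resting cells (1 array) and the other was cells exposed to oxygen-glucose deprivation (OGD), a culture model of ischaemia that withholds oxygen and glucose, for 3 h (1 array). The deposited values were linear intensities of 31042 probe sets besides 57 array controls, with a median of 19.6 on the resting array and 19.7 on the OGD array. These medians served as the floor of measurement. Of 14217 genes with a probe set naming them alone, 9580 were above the floor on at least 1 array and 9168 on both. With 1 array per group there were no replicates, so no difference below carries a test or an error across cultures, and all differences describe these 2 arrays.

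The comparison asked which transcripts differed by 1.5-fold or more between OGD-exposed and resting cells. Arhgap5, which encodes a GTPase-activating protein, was 1.96-fold higher on the OGD array, at an intensity of 183.0 against 93.4. The zinc finger genes Zfp654 and Zfp638 were 1.79-fold and 1.70-fold higher, and all 3 probe sets of Zfp638 were higher, the other 2 by 1.71-fold and 1.50-fold. Adra1b, which encodes an adrenergic receptor, was 1.63-fold lower on the OGD array, and Scamp4, a secretory carrier membrane protein, was 1.59-fold lower. The OGD value of Adra1b lay just above the floor, at 19.725 against 19.659. Altogether 7 genes were higher and 4 were lower by 1.5-fold or more, which is 0.115% of the measured genes. In these values 0 genes differed by 2-fold in either direction. The 412 genes above the floor on 1 array only entered with bounds, so a 2-fold difference among them could go unseen.

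The remaining genes past 1.5-fold on the higher side were Dsc1, a desmosomal cadherin (1.55-fold), Phip, a protein that binds insulin receptor substrate (1.55-fold), Chm, a Rab escort protein (1.52-fold), and the uncharacterised locus LOC102553465, with a log2 difference of 0.77. On the lower side were Apol9a, of the apolipoprotein L family, at least 1.57-fold lower, and Acat2, an acetyl-CoA acetyltransferase of sterol synthesis, at least 1.53-fold lower. Both of these were under the floor on the OGD array, so their values are bounds. Dsc1 and Chm were just above the floor of 19.6 at rest, each at 19.9. Zfp638 was the only one of these 11 genes with other probe sets above the floor on both arrays. Just inside the threshold were Pla2g2c (1.50-fold), a secreted phospholipase, Rb1cc1 (1.47-fold), a component of the complex that starts autophagy, Abhd14b (1.46-fold), the adherens junction gene Ctnna1 (1.46-fold), Cacfd1 (1.45-fold) and Ifngr2 (1.43-fold), a chain of the interferon gamma receptor, all higher on the OGD array.

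Genes just inside the threshold on the lower side were Tmed1 (1.50-fold), Phf20 (1.48-fold), the transcription factor Ascl2 (1.48-fold), Fam149b1 (1.48-fold), the neutrophil-attracting chemokine Cxcl3 (1.46-fold), Zfp668 (1.45-fold), Sh3d21 (1.44-fold), Trim39 (1.44-fold), Gmppb (1.44-fold) and Mrnip (1.42-fold). For Phf20 another probe set above the floor had a log2 difference of 0.08, for Gmppb another had -0.002, and for Cxcl3 the other 2 had -0.15 and -0.14. Among genes above the floor on 1 array only, Lrrc14 was at least 1.43-fold higher on the OGD array, Cdk5r1 at least 1.42-fold, Tmem170a at least 1.38-fold and Swt1 at least 1.37-fold. The serotonin receptor gene Htr2a had a log2 difference of -0.49 or beyond, and Sts, the steroid sulfatase gene, was at least 1.38-fold lower.

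**Figure D1:**
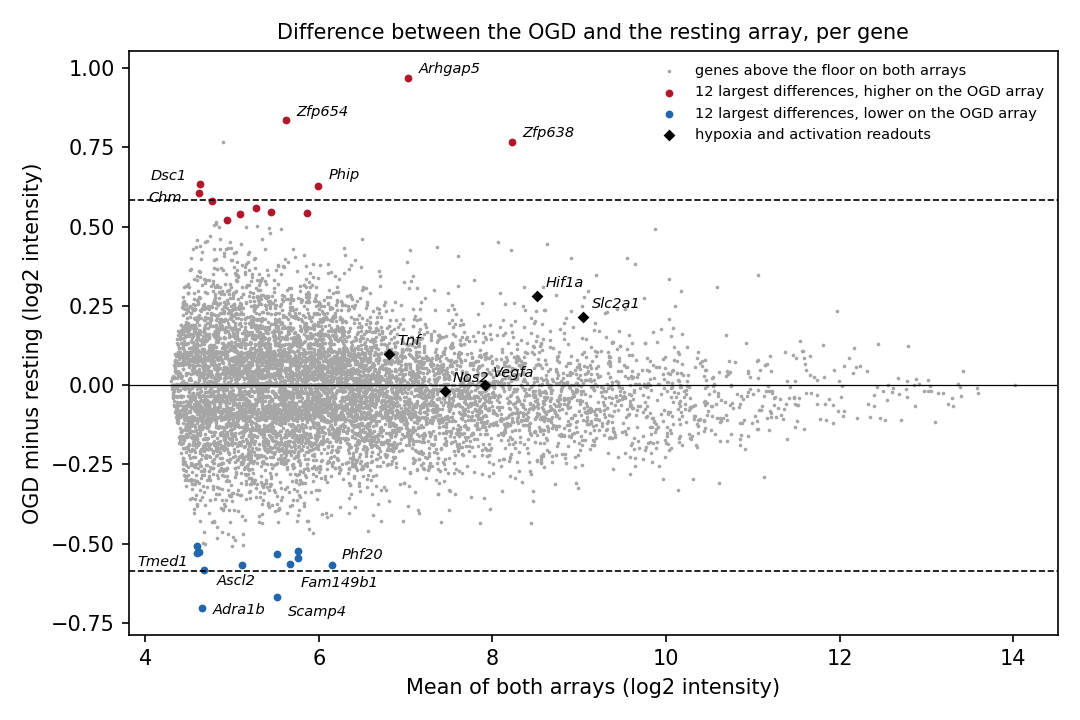
Each grey point is 1 of the 9168 genes above the floor on both arrays, with the mean log2 intensity of both arrays on the x axis and the log2 difference, OGD minus resting, on the y axis. Dashed lines mark 1.5-fold, red and blue points are the 12 genes furthest apart in each direction among genes with an established symbol, black diamonds are hypoxia and activation readouts, and Arhgap5 lies highest at a difference of 0.97.

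Genes for hypoxia-related transcription factors and genes that report microglial activation lay inside the threshold wherever they were measured. Hif1a, the oxygen-regulated transcription factor subunit, was 1.22-fold higher on the OGD array and its relative Epas1 1.19-fold higher, although the other probe set of Epas1 had a log2 difference of -0.08. Vegfa, an angiogenic growth factor induced by hypoxia, had an intensity of 240.7 on both arrays, and its other probe set 71.9 on both. Exactly equal values were found for 8.70% of all probe sets, for a reason not given. Those of Vegfa may therefore not show an unchanged level. The inflammatory cytokine gene Tnf had a log2 difference of 0.10 and the inducible nitric oxide synthase gene Nos2 of -0.02, which became 0.009 with quantile or loess scaling. The microglial markers Aif1 and Itgam had -0.04 and -0.11, and the other probe set of Aif1 had -0.35. Tlr4, Il1b, Il6, Arg1 and Arnt were under the floor on both arrays and are given no fold. Among reference genes Hprt1 had 0.06, Tbp -0.13 and B2m 0.13, while Actb, Gapdh and Ppia had no probe set outside the controls that named them alone. The value of B2m was just above the floor, at 19.8 at rest against 19.6.

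Of 28 gene lists, 27 had at least 5 measured members, and 2 of these had a median outside the central 95% of 10000 brightness-matched random lists, where 1.35 would be expected by chance alone. Interferon-stimulated genes, which carry the antiviral response, had a median log2 difference of -0.12 over 18 measured members, at percentile 0.28 of the random lists. Of these, 11 were lower and 7 higher on the OGD array, with none past 1.5-fold. The immunoproteasome subunit Psmb9 was 1.35-fold lower, the exonuclease Isg20 1.31-fold lower and the antiviral enzyme Rsad2 lower with a log2 difference of -0.33, while Ifit1 had a difference of 0.31 in the other direction. Without Psmb9 the percentile was 6.08, inside the central 95%, and it was 4.64 with a lower floor and 3.57 with a higher one. The middle members had log2 differences of -0.155 and -0.076, so leaving out any member below the middle gives the same median as leaving out Psmb9.

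Genes of autophagy and the lysosome had a median difference of 0.030 over 28 measured members, at percentile 97.82, with 18 higher, 9 lower and none past 1.5-fold. Sqstm1, an autophagy receptor, was 1.29-fold higher on the OGD array, and its other 3 probe sets above the floor had log2 differences of 0.29, 0.14 and 0.18. Wipi1, which acts in autophagosome formation, was 1.22-fold higher and the lysosomal protease Ctsd 1.19-fold higher, while Atg7, an enzyme of autophagosome assembly, had a log2 difference of -0.26 in 1 probe set and 0 in another. The median was 0.061 after quantile or loess scaling. Without Sqstm1 the percentile was 97.48, which is inside the central 95%, and against random lists not matched on brightness it was 93.03.

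The list of hypoxia-induced targets of HIF had a median of -0.021 over 27 measured members, at percentile 36.64, with 9 higher, 15 lower and 3 equal. The glycolytic regulator Pfkfb4 was 1.28-fold lower on the OGD array, Ankrd37 was 1.23-fold lower, and the haem oxygenase gene Hmox1 was 1.16-fold higher. In the next brightest probe sets, measured for 10 of the list's members, the median was 0.10 at percentile 97.74. Glycolysis and glucose uptake had a median of 0.015 (percentile 87.41), with Gys1, the glycogen synthase gene, 1.26-fold higher and the glucose transporter gene Slc2a1 1.16-fold higher. Tpi1 was 1.17-fold lower, near the floor at an intensity of 28.2 at rest. With the higher floor the glycolysis list stood at percentile 99.56. Targets of the stress factor ATF4 had a median of 0 (percentile 73.6), with Aldh18a1 1.23-fold and Chac1 1.19-fold higher and Trib3 at a log2 difference of 0.26, although the other 2 probe sets of Trib3 had 0.015 and 0.013. Chaperones of the endoplasmic reticulum had 0.0084 (percentile 90.72), where Pdia3 and Pdia6 were 1.12-fold and 1.10-fold higher and Manf 1.12-fold lower, with a log2 difference of -0.064 in the other probe set of Pdia3. Heat shock proteins had 0.012 (percentile 86.36), and -0.004 with the higher floor, with Dnajb1 1.26-fold higher, Cryab 1.14-fold higher and Hspe1 1.05-fold lower, while the other probe set of Dnajb1 had -0.009. NRF2 antioxidant genes had 0.014 (percentile 88.69), with 13 higher, among them Sqstm1 and Hmox1, and 9 lower, among them Gstp1 (1.18-fold). With the mean over the probe sets of each gene the NRF2 list had 0.043, at percentile 98.46.

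Immediate early genes had a median of -0.0022 (percentile 67.75), and 0.017 after quantile or loess scaling, with Dusp1 1.14-fold higher and Dusp6 and Jun 1.12-fold and 1.11-fold lower. The other probe sets of Dusp6 had log2 differences of 0.10 and -0.066, and those of Jun 0.009 and 0.008. Inflammatory cytokines and NF-kB targets had 0.022 (percentile 85.94), where the prostaglandin E synthase gene Ptges was 1.24-fold higher, Tlr2 1.16-fold higher and Saa3 1.16-fold lower. Chemokines and their receptors had -0.067 (percentile 14.03), with Ccl5 1.11-fold and Cxcr4 1.10-fold lower beside Cxcl3. The Toll-like receptor pathway had 0.024 (percentile 78.11), with Casp1 1.11-fold and Irak1 1.09-fold higher (-0.12 in the other probe set of Irak1), and it stood at percentile 97.79 with the higher floor. Markers of alternative activation had 0.072 (percentile 93.68), with the lectin genes Clec7a and Clec10a 1.16-fold and 1.13-fold higher and Il1rn 1.14-fold lower. Genes of homeostatic microglia had -0.058 (percentile 15.36), and -0.0087 at percentile 58.56 with the higher floor, where the purinergic receptor genes P2ry12 and P2ry6 had log2 differences of -0.26 and 0.24 and Mef2c was 1.14-fold lower. Pan-myeloid markers had -0.044 (percentile 21.62), with C1qc and Cd37 1.23-fold and 1.21-fold higher and Cybb 1.14-fold lower. Complement, MHC and phagocytosis genes had 0.025 (percentile 88.34), with Cd9 1.15-fold higher and C1qa 1.14-fold lower.

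Oxidative phosphorylation had a median of -0.060 (percentile 11.02), with 32 of 41 members lower on the OGD array, among them Sdhb (log2 difference -0.26), Ndufb10 (-0.26) and Ndufb8 (-0.25). Cytosolic ribosomal proteins had -0.030 (percentile 58.44), and 0.004 after loess scaling, with 32 of 39 members lower, among them Rps13 (1.22-fold), Rpl23a (1.10-fold) and Rps3 (1.08-fold). The probe set of Rps13 was near the floor, at 24.9 at rest, against 2236.1 for Rpl23a and 6947.2 for Rps3. Bright random lists were also lower, with a median of -0.031 for the size of the oxidative phosphorylation list and -0.034 for that of the ribosomal list. Cholesterol biosynthesis had 0 (percentile 59.63), with Idi1 1.21-fold higher and Tm7sf2 1.14-fold lower besides Acat2. Cell cycle genes had 0.014 (percentile 89.38), and -0.026 in the next brightest probe sets, with Ccne2, Cenpe and Mcm5 1.28-fold, 1.27-fold and 1.23-fold higher. Genes of p53 signalling and apoptosis had 0.021 (percentile 86.69), and -0.039 in the next brightest probe sets, where Bid and Ei24 were 1.26-fold and 1.17-fold lower and Bad 1.17-fold higher. Only 4 histone genes were measured, too few for a percentile, and of these H1f4, H2ac1 and H2ax had log2 differences of -0.26, -0.26 and -0.044.

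Markers of other cell types were included because a microglial culture can hold such cells. Several named markers lay near the floor of 19.6 at rest, among them Gfap at 27.4, Slc1a2 at 23.8 and Ina at 20.8. So did Cspg4 at 21.1, Col6a2 at 23.1 and Cd3e at 24.3. Others were brighter, such as Glul at 152.3, Elavl3 at 117.0 and Esam at 89.0. Whether such cells were present was not tested. Astrocyte markers had a median of -0.0099 (percentile 42.79), and 0.0008 after loess scaling, with Gfap 1.35-fold and Slc1a2 1.35-fold higher and Glul 1.16-fold lower in its brightest probe set, the others having 0.084 and 0. Oligodendrocyte lineage markers had -0.020 (percentile 34.61), and 0.059 without a floor, with Mbp 1.17-fold higher and Cspg4 and Sox10 1.06-fold and 1.05-fold lower. Neuron markers had 0.11 (percentile 94.14), with Syn1 1.18-fold and Ina 1.08-fold higher and Elavl3 1.08-fold lower. Fibroblast and meningeal markers had 0.077 (percentile 94.0), with Igfbp5 1.21-fold and Col6a2 1.18-fold higher and Thy1 1.28-fold lower; against unmatched random lists they stood at percentile 97.57. Endothelial and mural markers had -0.0094 (percentile 46.43), and 0.0086 to 0.017 under 4 alternatives in floor or probe sets, with Vwf 1.22-fold and Des 1.17-fold higher and Esam 1.08-fold lower. The list of lymphocyte and granulocyte markers had 0.043 (percentile 72.46), with Cd4 1.08-fold higher, Cd3e 1.07-fold higher and Cd8b at least 1.07-fold lower. Cd4 was the brightest of these, at 67.2 at rest, and the arrays do not tell which cells it came from. Across all 28 lists 497 distinct genes were measured, of which 0 were higher and 1, Acat2, was lower by 1.5-fold or more.

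**Figure D2:**
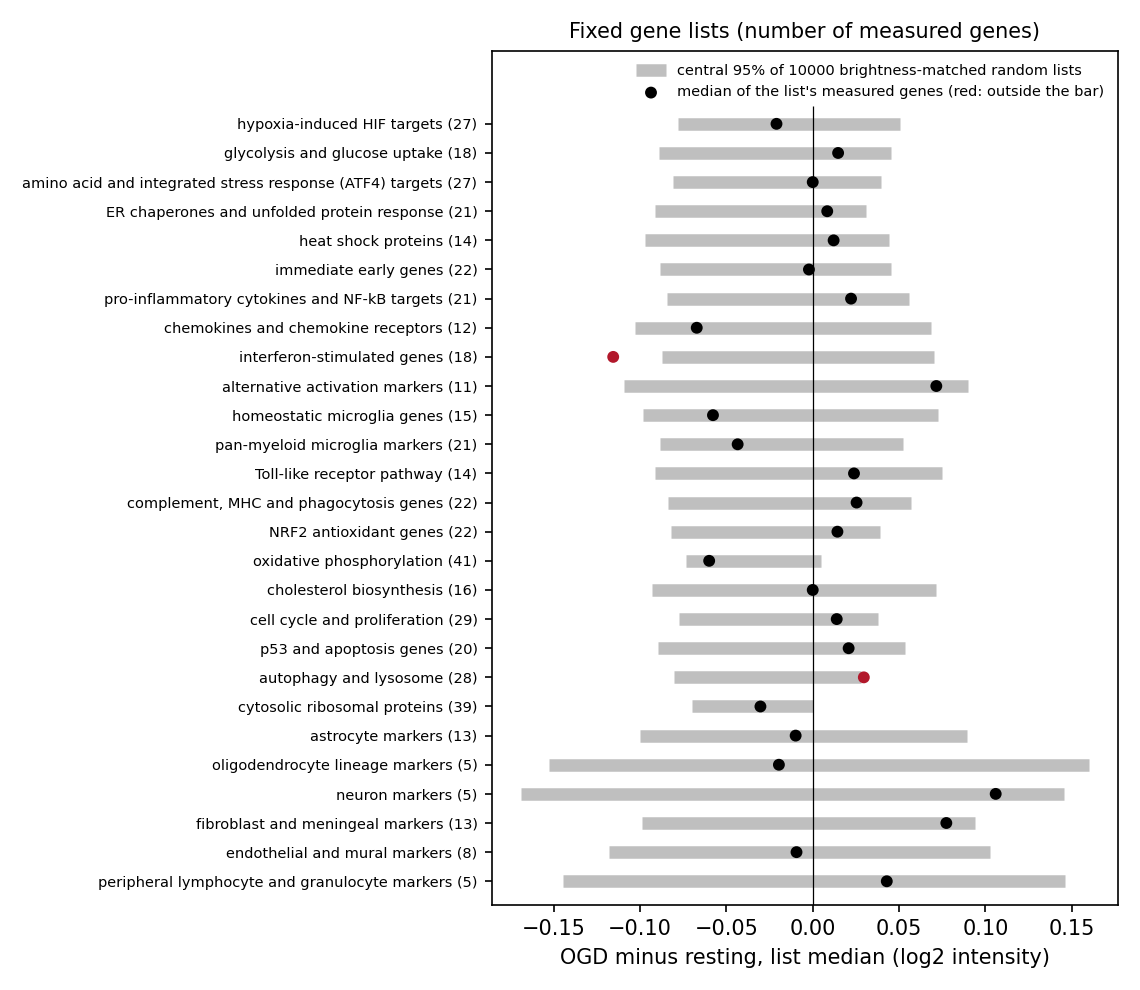
Each point is the median log2 difference, OGD minus resting, of the measured genes of 1 list, with their number in parentheses, and each grey bar is the central 95% of the medians of 10000 brightness-matched random lists. The 2 red points, interferon-stimulated genes at -0.12 and autophagy and lysosome at 0.030, lie outside their bars.

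Both arrays were close over all genes above the floor on both: the SD of the differences was 0.148, 92.5% of genes lay within 1.2-fold, and Pearson's r of the log2 values across genes, which are not independent replicates, was 0.996. Probe sets of 1 gene differed among themselves with an SD of 0.147 over 1902 genes. The SD over all these probe sets together was 0.154, so most of this total spread was also present within genes. Control probe sets for beta-actin and Gapdh had median differences of 0.11 and 0.11, hybridisation spike-ins -0.069 and poly-A spike-ins -0.085. The ratio of 3 prime to 5 prime signal was 3.33 on the resting and 3.28 on the OGD array for beta-actin, and 1.97 and 2.04 for Gapdh. The log2 change of this ratio was -0.079 and -0.047 for the poly-A spike-in dap and 0.25 and at least 0.94 for the spike-in lys, each on a pair of control sets.

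The number of genes past 1.5-fold depended on the floor, with 23 higher and 14 lower at the lower floor, 4 and 0 at the higher one, and 35 and 23 without a floor. A difference for a single gene in this range has no replicate check.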

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

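Tests chosen only after the result was seen were the use of the hypoxia list to weigh scaling, in which the scalings were planned and the next brightest probe sets were not, the correlations between probe sets of a gene, the comparison of 3 prime with 5 prime signal and the use of the higher floor to weigh dimness. The other tests of gene span and of the interferon list were written down before their values were known, but how the interferon values were read was changed afterwards.

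Probe sets that the annotation leaves unnamed or assigns to several genes were not used in the comparison, and of 3777 such probe sets above the floor 5 were higher and 1 was lower by 1.5-fold or more on the OGD array. The largest was 2.26-fold higher. The share past the threshold was 0.159%, against 0.163% of 12231 probe sets naming 1 gene.

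Few genes differed between the arrays, with 7 higher and 4 lower by 1.5-fold. Noise of single probe sets as the whole of the differences is argued against by the correlation of differences between probe sets of 1 gene, 0.071 (bootstrap interval 0.025 to 0.119 over 1902 genes, highest of the shuffled values 0.065), which was 0.064 (0.014 to 0.115) over 1698 genes with plain suffixes alone; a correlation this small still leaves most of each difference unshared. Arrays carrying RNA of the same treatment state cannot be told apart from an OGD effect on few genes, because the same 0.071 could come from labelling or hybridisation shared by the probe sets of a gene. Scaling that hid higher hypoxia genes such as Hmox1 stays open too: the hypoxia list stood at percentile 36.6, and at 36.64 to 53.14 across scalings, but the next brightest probe sets of 10 members stood at 97.74. An effect of OGD, the difference named by the design, stays open and untested without replicates.

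Of the 12 named genes furthest above rest, such as Arhgap5, 8 had a genomic span over the median, against 5 of the 12 furthest below. Over 9163 genes Spearman's rho between the difference and the genomic span of the gene in GRCr8 was 0.08 (0.059 to 0.101), and 0.076 with the brightness trend removed; across genes, which are not independent, this interval spans the bound of 0.1 set for the test, so a difference between the arrays that grows with span cannot be told apart from a smaller relation. A large difference in RNA integrity is argued against by beta-actin and Gapdh. Their ratio of 3 prime to 5 prime signal changed by at most 0.05 on the log2 scale. The poly-A spike-ins were mixed, with changes of 0.25 and at least 0.94 for lys and of -0.079 and -0.047 for dap. A small difference in integrity stays open, since the medians of the longest and shortest genes differed by only 0.032. With genes split by span into groups of like size, the median log2 difference was -0.0324 in the shortest group and -0.0111 in the next. It was 0 in both groups of longer genes. Of probe sets above the floor on both arrays 6.66% had exactly equal values, which can hold a median at 0. Equal medians therefore do not show that the longer groups were alike. An OGD effect that varies with gene span may also give this relation and was not tested.

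The interferon-stimulated list had a median of -0.12, with 11 of 18 members lower, such as Psmb9 and Isg20, and 7 higher, such as Ifit1 and Stat2, and its percentile of 0.28 became 6.08 without Psmb9 and 4.64, 3.57 and 3.22 with other floors or none. Dimness of members stays open. The 13 brighter members had a median of -0.033 at percentile 33.47, inside the central 95%, which met what was written beforehand for dimness. The 12 left by the higher floor had -0.094 at percentile 3.57, also inside, though this median stayed near that of the full list. With members on both sides of 0 a single gene moves the median. Noise of the probe set chosen for each member stays open, since only 1 member had another probe set above the floor, under the minimum of 5 for a percentile. An OGD effect stays open as well, and no test here separates it from these.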

How the results depend on the processing

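The next brightest probe sets are an alternative chosen after the result was seen; the other alternatives were planned. No paired analysis was possible because each group has 1 array and the results come from no test. None of Arhgap5, Zfp654, Zfp638, Dsc1, Phip, Chm, Adra1b, Scamp4, Apol9a and Acat2 changed direction in any alternative that gave it a value. Except for Zfp638, none of these had another probe set above the floor on both arrays. For them the alternatives reused the same probe set and could hardly reverse a difference of this size, so this is no check of direction. Inside the threshold Phf20 turned from -0.567 to 0.081 and Jun from -0.144 to 0.009 without shared-probe suffixes, and Nos2 from -0.017 to 0.009 after quantile or loess scaling. For single genes 1120 values stayed within the probe-set SD of 0.147 and 34 moved further, and for list medians 332 stayed within the spread of their random lists and 17 moved further. The counts of genes past 1.5-fold, 7 higher and 4 lower, were 23 and 14 with the floor at the 30th percentile, 4 and 0 at the 70th, 35 and 23 with no floor, 4 and 0 with a pseudocount, 16 and 10 per probe set with unnamed ones included, and 0 and 0 at 2-fold; requiring both arrays above the floor gave 2 lower, by leaving out the 2 bounds. Under centring, quantile and loess scaling 7 were higher and 5 lower. The interferon median was -0.0761 at the 30th percentile floor, -0.0759 with no floor, -0.1611 without shared-probe suffixes and -0.0761 without Psmb9. Its percentile was 4.64, 3.57, 3.22 and 6.08 with the floor at the 30th percentile, at the 70th, with no floor and without Psmb9. The autophagy median was 0.0611 after quantile, 0.0614 after loess scaling and 0.1064 in the next brightest probe sets. Its percentile was 93.03 against unmatched lists, 97.48 without Sqstm1, 97.48 without shared members and 96.8 in the next brightest probe sets. Lists outside the central 95%, 2 in the main setting, numbered 3 with the 70th percentile floor (glycolysis 99.56, Toll-like receptor pathway 97.79 and autophagy 97.94, the interferon list being inside) and 3 with the mean over probe sets (interferon 0.15, NRF2 98.46, autophagy 98.63). Against unmatched lists they were the interferon list at 0.29 and fibroblast markers at 97.57, and in the next brightest probe sets the hypoxia list at 97.74. They numbered 1 with the 30th percentile floor, 1 with no floor, 0 without each list's largest member, 1 without shared members and 1 in the next brightest probe sets. Some settings scored fewer lists. In the next brightest probe sets only the hypoxia, immediate early, cell cycle, p53 and autophagy lists had enough members. The oligodendrocyte, neuron and lymphocyte lists had too few with the 70th percentile floor and without each list's largest member. Where construction does not show the cause, the cause was not tested. Differences were wider near the floor. Among genes above it on both arrays their SD was 0.170 in the dimmest and 0.122 in the brightest 25%, with 4 and 2 genes past 1.5-fold.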

Other observations

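The tests in this part were all chosen after the data were seen. Genes with several probe sets above the floor on both arrays were searched for those with every such probe set apart by a log2 difference of 0.32 or more in 1 direction. Zfp638, Stag2, a cohesin subunit gene, and Ppp4r3b, a regulatory subunit gene of protein phosphatase 4, were higher on the OGD array, with the 2 probe sets of Stag2 1.29-fold and 1.41-fold higher and those of Ppp4r3b 1.30-fold and 1.37-fold higher. These 3 genes among 1902, with 0 lower, compare with a mean of 0.873 higher and a highest of 6 in 1000 shuffles of the differences among probe sets, so a count of 3 was within the range of the shuffles.

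Exactly equal intensities on both arrays were found for 2701 probe sets, 8.70% of all, and 1001 of these were above the floor, among them both probe sets of Vegfa. Among intensities over 100, 9.44% on the resting and 9.34% on the OGD array lay within 0.001 of a ladder with steps of 0.5 and a remainder of 0.165, where an even spread would give 0.4%. The summarisation that left these steps is not given in the sources used here.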
